A study of Sus scrofa with 120 samples.

How the data were processed

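Gene expression was measured by RNA sequencing in primary chondrocytes from pig femoral cartilage embedded in 2% agarose. The 120 libraries belong to 30 groups of 4, in a TRPV4 experiment (48 libraries) and a PIEZO1 experiment (72 libraries), each with harvests at 3 h and 9 h. Groups, times and replicate numbers were taken from the sample titles. Per the labels' protocols, the TRPV4 libraries were made by removing ribosomal RNA and priming with random hexamers, and the PIEZO1 libraries by a low-input kit from 10 ng of total RNA. All were sequenced as paired ends. The labels name polyA RNA as the molecule for every sample, which the TRPV4 protocol contradicts. Titles speak of transduction and the protocol of siRNA transfection. Small RNAs made up 6.23 ± 2.11% of the counts in DMSO libraries at 3 h (SD, n = 4) and 0.0203 ± 0.000524% in NT vehicle libraries at 3 h. The kits thus differ in what they capture, and levels were never tested between experiments.

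The authors deposited 1 table of counts, whole numbers per gene and library that are not normalised. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR to Sscrofa11.1 and counted with HTSeq. Versions and strand setting are not given in the sources used here. Without the latter, reads from overlapping genes on opposite strands cannot be told apart. The table held 32388 lines for 31907 gene identifiers, and the 481 repeated lines, which carried identical counts, were removed. A symbol came from the table for 16681 identifiers, from a gene name table for 822 and from a single Entrez match in the RefSeq gene table (Sscrofa11.1) for 761. Where several identifiers shared a symbol, the 1286 further ones kept their identifier as name. Every value column belonged to a sample. Positions are those of RefSeq on Sscrofa11.1, the build the notes name. Of counts from 1 to 20, most were even numbers (66.12 to 74.77% in TRPV4 libraries and 52.33 to 63.22% in PIEZO1 libraries), which the sources used here do not explain. Errors here come from the spread between libraries and not from counting statistics.

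Some gene models cover several genes, so that MMP3 also holds MMP1, IFIT1 also IFIT3, P3H1 also SLC2A1 and DHDH also BAX. These and near-identical families, such as metallothioneins, histones and small nucleolar RNAs, are uncertain where reads could be shared. Of the listed genes, 19 had no line of their own in the table, among them BTG2, HAS2, HSPA1A, CCNA2 and BMAL1, whose older symbol ARNTL was used.

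Total counts were 20651530 to 80223797 in TRPV4 libraries and 36807992 to 66240251 in PIEZO1 libraries. Replicates of a group never agreed within sampling noise. The chi-square per degree of freedom between 2 libraries of a group was at least 5.49 over 72 pairs in the TRPV4 experiment and at least 12.5 over 108 pairs in the PIEZO1 experiment, so none was treated as a copy of another. The common biological coefficient of variation was 0.107 and 0.0874 in the TRPV4 experiment at 3 h and 9 h, and 0.282 and 0.300 in the PIEZO1 experiment.

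Counts were analysed in R 4.3.3 with edgeR 4.0.16. For each experiment and time, libraries were scaled by the trimmed mean of M-values (TMM), low genes were removed with filterByExpr (minimum count 10), and 1 quasi-likelihood model with a term per group was fitted (estimateDisp, glmQLFit, glmQLFTest). This tested 16562, 16540, 18330 and 18611 genes in the TRPV4 experiment at 3 h and 9 h and the PIEZO1 experiment at 3 h and 9 h. Contrasts of 9 h against 3 h came from models of both times (17447 and 20202 genes). P-values were adjusted by Benjamini-Hochberg within each of 39 contrasts and called under 0.05 with no minimum fold. The standard error of a log2 fold change is its size divided by the square root of F. Replicate numbers were not used as a block. CPM are counts-per-million of the TMM-scaled total.

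The 24 gene lists, the 39 contrasts and their tests were fixed before the data were examined, and what was added later is named as such. The lists cover immediate early genes, calcineurin-NFAT and CREB targets, cartilage matrix genes, matrix-degrading enzymes, NF-kB and inflammatory genes, TGF-beta and BMP genes, YAP-TAZ targets, and SRF and actin genes. They also cover the unfolded protein and integrated stress response, heat shock, NRF2, p53, cell cycle, hypoxia and glycolysis, interferon, cholesterol synthesis and clock genes. The others are growth factors, mechanosensitive and calcium channels and pumps, hypertrophy and bone markers, and markers of fibroblasts, leukocytes, endothelium, and adipocytes and erythroid cells. Each was tested with camera at a preset correlation of 0.01 (limma 3.58.1), adjusted by Benjamini-Hochberg over all lists and contrasts of an experiment. Each was tested again with an estimated correlation and with fry, which asks only whether a list's genes move one way. Of 936 list tests 245 were called, and in 0 of these did the median, the mean and the test differ in sign.

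Signature scores are the mean log2 CPM (prior count 2) of the genes called higher for the named stimulus minus that of the genes called lower, less the mean score of the matching control libraries, and were compared by two-sided exact permutation of the 8 libraries (70 arrangements), with the control means taken as fixed. Overlaps between comparisons that share controls were set beside 10 simulations of unchanged groups against the same controls, the overlap of independent lists, and 3 divisions of the controls into pairs.

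Genes were named by a rule fixed before the data were examined. PIEZO1 and TRPV4 came first. Then, among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the 2 groups of 4, the 8 largest rises and falls were taken for GSK101, loading, IL-1, and Yoda1 and compression in NT, and the 4 largest for other contrasts. Members of the lists could be named in any contrast. Not every gene the rule allows is named.

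The test was tried on counts simulated from the means and library sizes of the real libraries. Variation shared across genes was not simulated and may add false calls. At 2-fold, 71.2% of changed genes were called for loading at 3 h (47 of 66, 11 false calls over 16212 genes). At 9 h it was 66.2% (45 of 68, 8 false calls over 16078). For compression in NT 51.7% were called at 3 h (30 of 58, 1 false call over 17782 genes). At 9 h it was 53.2% (33 of 62, 4 false calls over 18009).

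Alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, edgeR with RLE size factors, no filter on low counts, the replicate number as a block, only the 2 compared groups in the model, each library left out, other list tests, and other settings of the scores and overlaps. Alternatives added after the data were seen were protein-coding genes only, a replicate axis (the first principal component of deviations between replicates, taken from the libraries of the other time) as a covariate in the PIEZO1 experiment, GSK101 libraries thinned to the mean DMSO total at 3 h, all 3 stimuli together for PIEZO1, single libraries left out of 2 further counts, vehicle libraries left out of the scores, and scores of each library less 1 vehicle library of its state, over all 576 pairings. Dividing libraries into animals was not possible, and properties that need a genome sequence, such as GC content, were not analysed here.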

Results

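RNA-seq gene counts were obtained from primary pig chondrocytes, the matrix-making cells of cartilage, taken from femoral cartilage and cast in agarose as small cartilage constructs. The series addresses which genes respond when the calcium-permeable ion channels TRPV4 and PIEZO1 are opened, by a drug or by a mechanical stimulus. In the TRPV4 experiment, 48 libraries covered 6 conditions, harvested 3 h and 9 h after the start of stimulation. The conditions were a DMSO vehicle, the TRPV4 agonist GSK101 (1 nM), the TRPV4 antagonist GSK205 (10 uM), cyclic loading at 10% deformation for 3 h, loading with GSK205, and the inflammatory cytokine IL-1 (1 ng/mL). In the PIEZO1 experiment, 72 libraries crossed 3 transfection states with 3 stimuli at the same times. Cells were left non-transfected (NT), or received a non-targeting siRNA (siNTC) or siRNA against PIEZO1 (siPIEZO1). They were then kept in vehicle, compressed once to 80% deformation, which the labels call supraphysiologic, or treated with the PIEZO1 agonist Yoda1 (5 uM). Each of the 30 groups held 4 libraries. The sample labels give the GSK205 and Yoda1 doses in mM where the series description gives uM, and name IL-1a where the series description names IL-1.

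The experiments used different library kits, so levels were not tested between them. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples. A difference was called at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Values after a log2 fold change are standard errors, values after counts-per-million (CPM) are SDs, and n = 4 libraries per group unless stated. The lists of genes were fixed before the data were examined. List tests used camera, and each adjusted p given for a list was obtained with an estimated correlation between its genes, after a call with a preset correlation.

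PIEZO1 (ENSSSCG00000035230, chromosome 6, 914480 to 967113 of Sscrofa11.1), the target of the knockdown, was low in the PIEZO1 experiment. In vehicle libraries at 3 h it stood at 5.66 ± 0.753 CPM in NT, 5.63 ± 1.53 in siNTC and 4.77 ± 0.420 in siPIEZO1, and at 9 h at 4.54 ± 0.545, 5.49 ± 1.24 and 3.45 ± 1.10. The 4 siPIEZO1 vehicle libraries held 4.22, 5.01, 4.68 and 5.18 CPM at 3 h, inside the siNTC range of 3.71 to 6.99. At 9 h they held 2.24, 4.25, 4.52 and 2.80 CPM, against 3.80 to 6.48 in siNTC. The log2 fold change of siPIEZO1 against siNTC in vehicle was -0.24 ± 0.19 at 3 h (adjusted p = 0.58) and -0.66 ± 0.23 at 9 h (adjusted p = 0.062), so neither passed the test. Over the 3 stimuli together (12 against 12 libraries, a contrast added after the data were seen), PIEZO1 was lower by 25.7% at 3 h (log2 fold change -0.43 ± 0.11, adjusted p = 0.0066) and by 33.9% at 9 h (-0.60 ± 0.13, adjusted p = 0.0010). The loss of PIEZO1 mRNA was therefore partial in the libraries labelled siPIEZO1, and every direction below that is drawn from them carries that limit.

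TRPV4 (ENSSSCG00000009929, chromosome 14, 41125819 to 41169582) was expressed in both experiments, at 511 ± 36.5 CPM in DMSO and 223 ± 26.6 in NT vehicle at 3 h. PIEZO1 stood at 110 ± 14.6 CPM in the DMSO libraries of the TRPV4 experiment. IL-1 moved both channel genes at 9 h. TRPV4 fell to 239 ± 11.7 CPM from 603 ± 29.4 (log2 fold change -1.33 ± 0.06, adjusted p = 9.9e-20), and PIEZO1 rose to 160 ± 13.8 from 93.8 ± 2.79 (0.77 ± 0.08, adjusted p = 1.4e-09). Transfection with siNTC raised TRPV4 against NT in vehicle, by 0.44 ± 0.12 at 3 h and 0.57 ± 0.13 at 9 h on the log2 scale.

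**Figure D1:**
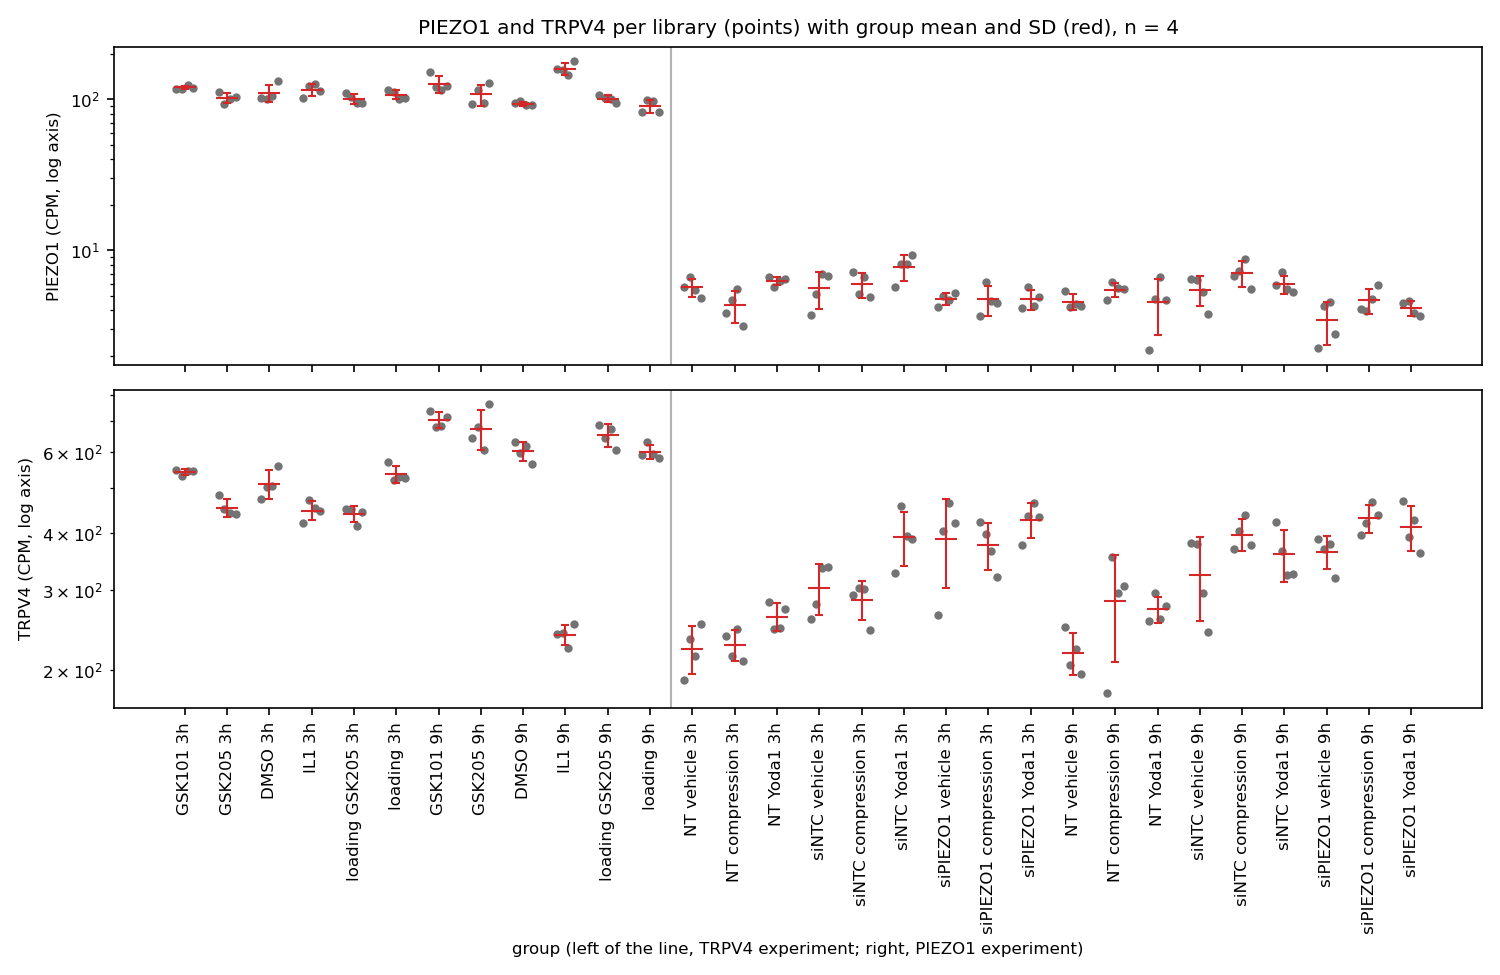
Normalised counts-per-million (CPM, log axis) of PIEZO1 and TRPV4 in each library (grey points), by group in both experiments, with group means and SDs in red (n = 4). PIEZO1 lay between 2.24 and 6.99 CPM in the vehicle libraries of the PIEZO1 experiment and averaged 110 CPM in DMSO at 3 h.

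GSK101 raised immediate early genes strongly at 3 h. FOS and FOSB, subunits of the AP-1 transcription factor, rose by 6.09 ± 0.08 and 8.02 ± 0.16 on the log2 scale, FOS from 78.3 ± 4.65 to 5341 ± 250 CPM. JUN (5.03 ± 0.12), EGR1 (4.17 ± 0.15) and the nuclear receptor NR4A1 (4.99 ± 0.18) rose with them. INHBA, which encodes the activin A subunit, rose by 5.15 ± 0.13, the pseudokinase gene TRIB1 by 5.18 ± 0.10 and the ciliogenesis factor FOXJ1 by 7.90 ± 0.22. In the list of immediate early genes 25 of 25 measured members rose (also adjusted over the list alone), with a median log2 fold change of 3.43 (adjusted p = 1.6e-04).

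Of the targets of calcineurin and CREB, which answer to calcium, 12 of 16 rose and 1 fell, 12 and 1 adjusted over the list alone (adjusted p = 6.9e-04). RCAN1, an inhibitor of calcineurin that is itself an NFAT target, rose by 3.54 ± 0.08 and NFATC2 by 3.39 ± 0.10. Of the growth factors 16 of 21 rose, 17 adjusted over the list alone (adjusted p = 0.010), including the EGF receptor ligands AREG (3.94 ± 0.31) and HBEGF (3.73 ± 0.19). Of the TGF-beta and BMP genes 20 of 27 rose and 4 fell, 20 and 4 adjusted over the list alone (adjusted p = 0.028). BMP2 rose by 3.50 ± 0.09, while ID3, a BMP target, fell by 1.13 ± 0.08. Of the NF-kB and inflammatory genes 25 of 31 rose and 1 fell, 27 and 1 adjusted over the list alone (adjusted p = 0.038). Among them were PTGS2, which encodes cyclooxygenase-2 (4.52 ± 0.14), and the cytokine genes LIF (4.22 ± 0.13) and IL6 (2.97 ± 0.12). Heat shock genes (14 of 16 rose, 14 adjusted over the list alone; adjusted p = 0.0097), SRF and actin genes (11 of 20 rose and 1 fell, 13 and 1 adjusted over the list alone; adjusted p = 0.030) and matrix-degrading enzymes (12 of 17 rose and 2 fell, 13 and 2 adjusted over the list alone; adjusted p = 0.022) rose too.

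Of 17 lists called, 8 were lost once the correlation was estimated. These included cholesterol synthesis genes, of which 14 of 21 rose, 14 adjusted over the list alone (adjusted p = 0.099 with an estimated correlation). They also included cartilage matrix genes (12 of 25 rose and 2 fell, 12 and 2 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), of which the aggrecan gene ACAN rose by 0.42 ± 0.06 and COL2A1, the main cartilage collagen, by 0.30 ± 0.07. In all, GSK101 called 6627 of 16562 genes at 3 h, 3640 higher and 2987 lower. The 8 largest falls under the naming rule were all small RNAs, such as SNORD94 (-2.77 ± 0.39) and the cartilage microRNA precursor MIR140 (-2.50 ± 0.18). The GSK101 libraries at 3 h were also deeper, at 62677053 to 80223797 counts against 20651530 to 29904509 in DMSO. Small RNAs made up 2.41 ± 0.589% of their counts against 6.23 ± 2.11% in DMSO (SD, n = 4). Mitochondrial ribosomal and transfer RNA made up 0.808 to 3.04% of their counts against 0.334 to 0.868% in DMSO. All ribosomal RNA, the mitochondrial included, made up 0.848 to 3.67% against 0.375 to 1.62%. The 2 shares both count mitochondrial ribosomal RNA, so they are not separate signs. Whether RNA quality or the removal of ribosomal RNA differed between these groups was not tested and stays open for all 3 h calls with GSK101.

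At 9 h with GSK101, INHBA rose by 6.51 ± 0.13, to 384 ± 14.8 CPM from 4.29 ± 1.01. The decoy IL-1 receptor gene IL1R2 rose by 6.89 ± 0.34, the plasminogen activator gene PLAT by 5.77 ± 0.19, the calcium-activated potassium channel gene KCNN4 by 5.60 ± 0.17 and the receptor gene GPRC5A by 5.46 ± 0.08. Falls were seen in the collagen gene COL19A1 (-3.45 ± 0.14), the BMP antagonist gene GREM1 (-2.38 ± 0.07), the cell division cycle associated gene CDCA7 (-4.02 ± 0.14) and the clock genes TEF (-3.17 ± 0.08) and NR1D1 (-2.98 ± 0.24). SOX6, a transcription factor of chondrocytes, fell by 1.40 ± 0.05, and COL2A1 (-0.38 ± 0.05) and ACAN (-0.25 ± 0.05) fell slightly.

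Immediate early genes stayed high (25 of 25 rose, 25 adjusted over the list alone; adjusted p = 0.011). TGF-beta and BMP genes (20 of 27 rose and 4 fell, 20 and 4 adjusted over the list alone; adjusted p = 0.0059), heat shock genes (14 of 16 rose, 14 adjusted over the list alone; adjusted p = 0.0092) and growth factors (14 of 21 rose and 3 fell, 14 and 3 adjusted over the list alone; adjusted p = 0.028) were called higher, with HSPH1 at 2.60 ± 0.05, FGF1 at 4.01 ± 0.19 and FGF18 at 3.73 ± 0.16. Matrix-degrading enzymes (12 of 18 rose and 3 fell, 12 and 3 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation) included MMP12 (4.16 ± 0.15), PLAU (4.09 ± 0.16), MMP3 (2.29 ± 0.10), whose gene model also covers MMP1, and MMP13 (2.03 ± 0.09). Of 12 lists called, 7 were lost with an estimated correlation. In all 10307 of 16540 genes were called, 4849 higher and 5458 lower.

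The direct test of the GSK101 effect at 9 h against 3 h called 7998 of 17447 genes, 4027 higher and 3971 lower. KCNN4 (4.41 ± 0.31) and the arginase gene ARG1 (3.96 ± 0.31) rose further, while the response of FOSB receded (-3.55 ± 0.16). Circadian clock genes fell in their response (2 of 17 rose and 12 fell, 2 and 12 adjusted over the list alone; adjusted p = 0.028).

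Cyclic loading at 10% deformation gave a smaller response at 3 h. FGF1, a fibroblast growth factor, rose by 3.08 ± 0.21, from 2.49 ± 0.669 to 21.0 ± 4.47 CPM. The cytokine genes IL11 and LIF rose by 2.67 ± 0.18 and 2.09 ± 0.13 and the EGF receptor ligand HBEGF by 2.10 ± 0.20. JUNB rose by 2.05 ± 0.11, INHBA by 1.76 ± 0.14 and PMEPA1, a TGF-beta target, by 1.61 ± 0.08. LMO1 (-2.98 ± 0.65), the clock repressor NR1D1 (-1.07 ± 0.20) and GAPDH, a common reference gene (-0.85 ± 0.17), fell. So did 5_8S_rRNA (-2.09 ± 0.58), SNORD15 (-1.18 ± 0.29) and MIR140 (-0.85 ± 0.17), but small RNAs made up only 3.42 to 4.50% of the loading libraries against 4.64 to 9.32% in DMSO, and their recovery was not tested here.

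Of the immediate early genes 17 of 25 rose and 1 fell, 19 and 1 adjusted over the list alone (median 0.52; adjusted p = 0.0044), with ATF3 at 1.55 ± 0.06 and IER3 at 1.48 ± 0.08. Cholesterol synthesis genes rose together (15 of 21 rose, 15 adjusted over the list alone; adjusted p = 0.030). Heat shock genes (9 of 16 rose, 11 adjusted over the list alone; adjusted p = 0.0097), unfolded protein response genes (10 of 22 rose, 16 adjusted over the list alone; adjusted p = 0.0089), TGF-beta and BMP genes (9 of 27 rose and 1 fell, 13 and 1 adjusted over the list alone; adjusted p = 0.030) and p53 genes (4 of 18 rose, 5 adjusted over the list alone; adjusted p = 0.030) were called higher, with DNAJA1 at 0.71 ± 0.07, TRIB3 at 0.61 ± 0.06, and SMAD7 and TGIF1, inhibitors of TGF-beta signalling, at 1.21 ± 0.11 and 1.26 ± 0.07. Hypertrophy and bone markers were called lower (3 of 10 fell, 4 adjusted over the list alone; adjusted p = 0.016), with RUNX2 at -0.66 ± 0.15, IHH at -0.57 ± 0.13 and MEF2C at -0.57 ± 0.06. Of 11 lists called, 4 were lost with an estimated correlation. Loading called 1683 genes at 3 h, 1302 higher and 381 lower, and 96 of them changed at least 2-fold. The count was 1110 without DMSO replicate 4, 1057 without loading replicate 3, and 1021 with only those 8 libraries in the model.

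At 9 h, when loading had stopped, FGF1 (1.62 ± 0.19), PMEPA1 (1.40 ± 0.10) and the osteoprotegerin gene TNFRSF11B (1.21 ± 0.06) were higher. So were CYP1A1 (1.60 ± 0.11) and CYP1B1 (1.28 ± 0.06), cytochrome P450 targets of the aryl hydrocarbon receptor. Immediate early genes now lay below DMSO (2 of 25 rose and 14 fell, 2 and 16 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation), with EGR1 at -0.99 ± 0.09. Circadian clock genes fell (10 of 17 fell, 11 adjusted over the list alone; adjusted p = 0.028), with PER2 at -0.64 ± 0.16 and NR1D1 at -0.67 ± 0.19. In all 3926 genes were called, 2068 higher and 1858 lower. The test of 9 h against 3 h called 1761 genes, 871 higher and 890 lower (1129 without loading 3 h replicate 1). The response receded for IL11 (-2.51 ± 0.23), JUNB (-2.17 ± 0.14), HBEGF (-2.07 ± 0.25) and ATF3 (-1.89 ± 0.08). Immediate early genes (20 of 25 fell, 22 adjusted over the list alone; adjusted p = 1.0e-04) lost response between the times.

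GSK205, the TRPV4 antagonist, was itself active without loading. At 3 h the nuclear receptor genes NR4A1 and NR4A3 rose by 2.14 ± 0.17 and 1.92 ± 0.15, and the kinase gene SIK1 by 2.07 ± 0.13. The metallothionein gene MT1A, one of a family of near-identical genes that can share reads, rose by 1.60 ± 0.19, while SMAD7 (-1.69 ± 0.13), FOSB (-1.62 ± 0.17) and ID3 (-1.53 ± 0.08) fell. Of 4 lists called, 0 held with an estimated correlation, and they included unfolded protein response genes (11 of 22 rose and 2 fell, 12 and 4 adjusted over the list alone; adjusted p = 0.055 with an estimated correlation). At 9 h MT1A rose by 2.80 ± 0.14 and TIPARP by 1.26 ± 0.08, and the hedgehog receptor gene PTCH1 (-1.10 ± 0.10) and the cartilage cytokine gene CYTL1 (-1.09 ± 0.09) fell. GSK205 called 4488 genes at 3 h (2415 higher, 2073 lower) and 3510 at 9 h (1997 higher, 1513 lower). At 3 h DESeq2 gave 4535 (2252 higher, 2283 lower) and protein-coding genes alone gave 4125 (1846 higher, 2279 lower), so no direction prevailed.

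Adding GSK205 to loading lowered several of the genes that loading raised. At 3 h, against loading alone, IL11 fell by 2.24 ± 0.17, as did INHBA (-1.96 ± 0.13) and SOCS3 (-1.93 ± 0.08), a feedback inhibitor of cytokine signalling. NR4A1 rose by 1.59 ± 0.16. Unfolded protein response genes were called higher (9 of 22 rose, 12 adjusted over the list alone; adjusted p = 0.0059). TGF-beta and BMP genes were called lower (3 of 27 rose and 10 fell, 4 and 11 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), and 6 of the 7 lists called were lost in this way. This comparison called 2529 genes at 3 h (1177 higher, 1352 lower) and 678 at 9 h (349 higher, 329 lower). The 3 h count was 1596 without loading replicate 1, and by DESeq2 2951 (1535 higher, 1416 lower), so no direction prevailed. The 9 h count was 295 and 347 without loading with GSK205 replicates 1 and 3, 320 without loading replicate 1, and 1181 by DESeq2.

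Loading still raised genes when GSK205 was present. Against GSK205 alone, JUNB rose by 2.87 ± 0.12 at 3 h, SMAD7 by 2.42 ± 0.12, the Notch target HES1 by 2.39 ± 0.20 and FGF1 by 2.28 ± 0.22. Immediate early genes (17 of 25 rose, 17 adjusted over the list alone; adjusted p = 0.0017), cholesterol genes (15 of 21 rose and 1 fell, 16 and 1 adjusted over the list alone; adjusted p = 0.030) and unfolded protein response genes (10 of 22 rose, 11 adjusted over the list alone; adjusted p = 0.0097) were called higher. At 9 h FGF1 (2.28 ± 0.21), TNFRSF11B (1.44 ± 0.06) and cholesterol genes (17 of 21 rose and 1 fell, 18 and 1 adjusted over the list alone; adjusted p = 0.035) were higher, and immediate early genes (17 of 25 fell, 20 adjusted over the list alone; adjusted p = 0.013) lower. These contrasts called 1975 genes at 3 h (1255 higher, 720 lower) and 2981 at 9 h (1459 higher, 1522 lower).

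The interaction tests whether the loading effect itself differed with GSK205. At 3 h it was smaller for INHBA (-1.66 ± 0.21), IL11 (-1.34 ± 0.28) and PTGS2 (-1.16 ± 0.23), and larger for JUNB (0.82 ± 0.16) and FOS (0.61 ± 0.09). The 4 largest rises under the naming rule were small RNAs, SNORD33 (2.68 ± 0.45), SNORD15 (2.41 ± 0.41), SNORD22 (1.92 ± 0.47) and SNORA63 (1.92 ± 0.42), whose shares of the counts differed between these groups (3.92% in loading, 5.18% with GSK205 added). It passed the test for 372 genes (148 higher, 224 lower), 288 (157 higher, 131 lower) with RLE scaling, 308 (177 higher, 131 lower) among protein-coding genes and 685 by DESeq2. With 1 library left out the count lay between 135 (without loading with GSK205 replicate 1) and 671 (without DMSO replicate 1). For 767 genes (368 higher, 399 lower) it passed at 9 h, with MT1A at -1.69 ± 0.19 and the cadherin gene FAT4 at 1.02 ± 0.13. This count was 505 without DMSO replicate 2. NF-kB genes (12 of 32 fell, 15 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation) and p53 genes (4 of 18 fell, 6 adjusted over the list alone; adjusted p = 0.036) were called lower at 9 h. Each library's GSK101 score, relative to DMSO, was the mean log2 CPM of genes called higher with GSK101 minus that of genes called lower. At 3 h the score was 0.22 ± 0.09 with loading and GSK205 and 0.31 ± 0.06 with loading alone (SD, n = 4 each, two-sided exact permutation p = 0.17), on a scale where GSK101 libraries scored 1.25 ± 0.06 and GSK205 alone 0.30 ± 0.06. Taken on the 100 called genes of smallest p, the 3 h difference was -0.19 (exact permutation p = 0.029), so the score gives no settled answer at 3 h. At 9 h both loaded groups scored 0.22 (exact permutation p = 0.94).

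IL-1, the inflammatory comparator, raised cytokine and protease genes steeply. At 3 h IL6 rose by 7.27 ± 0.13 and the chemokine gene CXCL2 by 7.11 ± 0.14, TNF by 7.08 ± 0.37, the aggrecanase gene ADAMTS4 by 7.81 ± 0.26 and the small GTPase gene RND1 by 7.18 ± 0.14. The adhesion molecule gene SELE was at 0 in the 4 DMSO libraries and at 6.30 ± 0.924 CPM with IL-1. SOX8 and SOX9, transcription factors of chondrocytes, fell (log2 fold changes -1.92 ± 0.08 and -0.60 ± 0.07). Every measured NF-kB gene passed the test (31 of 31 rose, 31 adjusted over the list alone; median 4.22; adjusted p = 5.3e-04). Matrix-degrading enzymes (10 of 17 rose and 3 fell, 11 and 4 adjusted over the list alone; adjusted p = 0.0059), immediate early genes (18 of 25 rose and 4 fell, 18 and 4 adjusted over the list alone; adjusted p = 0.018) and calcineurin and CREB targets (10 of 16 rose and 2 fell, 10 and 2 adjusted over the list alone; adjusted p = 0.018) were called higher. MMP13 rose by 3.85 ± 0.13 and MMP3 by 4.03 ± 0.13. IL-1 called 5341 genes at 3 h, 3064 higher and 2277 lower.

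At 9 h IL6 had reached 4918 ± 234 CPM from 4.57 ± 0.684 in DMSO (10.07 ± 0.14). CCL20 rose by 9.32 ± 0.13, CXCL8 by 8.50 ± 0.13 and ARG1 by 8.91 ± 0.12. The proteases that break down cartilage matrix rose steeply, MMP12 by 8.99 ± 0.16, MMP13 by 8.17 ± 0.10, MMP3 by 7.36 ± 0.12, ADAMTS4 by 7.97 ± 0.21 and ADAMTS5 by 7.04 ± 0.17 (12 of 18 rose and 4 fell, 12 and 4 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation). NOS2, the inducible nitric oxide synthase, rose by 7.55 ± 0.09. NF-kB genes (32 of 32 rose, 32 adjusted over the list alone; adjusted p = 0.0097), NRF2 genes such as HMOX1 at 4.95 ± 0.07 (17 of 18 rose and 1 fell, 17 and 1 adjusted over the list alone; adjusted p = 0.026) and hypoxia and glycolysis genes such as LDHA at 3.90 ± 0.05 (16 of 19 rose, 16 adjusted over the list alone; adjusted p = 0.030) were called higher. Hypertrophy and bone markers were called lower (1 of 10 rose and 8 fell, 1 and 8 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation), with IHH at -3.60 ± 0.20, but SPP1, the osteopontin gene of that list, rose by 2.87 ± 0.09. COL2A1 (-0.15 ± 0.05) and ACAN (-0.18 ± 0.05) fell slightly, and SOX6 (-1.61 ± 0.05), GREM1 (-3.74 ± 0.08) and CDCA7 (-5.24 ± 0.15) fell further. Among channel genes TRPC6 rose by 7.36 ± 0.37, the connexin gene GJA1 by 3.74 ± 0.06 and PIEZO2 by 1.86 ± 0.06. In all 10764 of 16540 genes were called, 5061 higher and 5703 lower. The test of 9 h against 3 h called 6775 (3223 higher, 3552 lower).

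The responses to GSK101, loading and IL-1 were measured against the same DMSO libraries, which makes their fold changes correlate by themselves. At 3 h 918 genes were called higher with both GSK101 and loading and 204 lower with both, where independent lists of those sizes would share 286 and 68.7. The correlation across genes was 0.49, and unchanged groups simulated against the same controls gave 0.55. The covariance was 0.127 against 0.0374 in the simulation. With the controls divided so that each comparison kept its own pair, 379 genes were higher in both, where 90.1 were due to independent lists, and the correlation was 0.18. At 9 h GSK101 and IL-1 shared 3219 genes called higher and 3782 called lower, where independent lists would share 1484 and 1882. The correlation was 0.57 against 0.51 simulated, the covariance 0.660 against 0.0304, and with divided controls the correlation was 0.48. GSK101 and loading at 9 h shared 1274 and 999 (606 and 613 for independent lists), with a correlation of 0.34 against 0.51 simulated and a covariance of 0.148 against 0.0297. Loading and IL-1 shared 1094 and 804 (633 and 641 for independent lists), and 1098 were called in opposite directions (1282). Their correlation was 0.19 against 0.53 simulated and their covariance 0.102 against 0.0343. Genes are not independent replicates, and 10 simulations and 3 divisions were drawn.

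**Figure D2:**
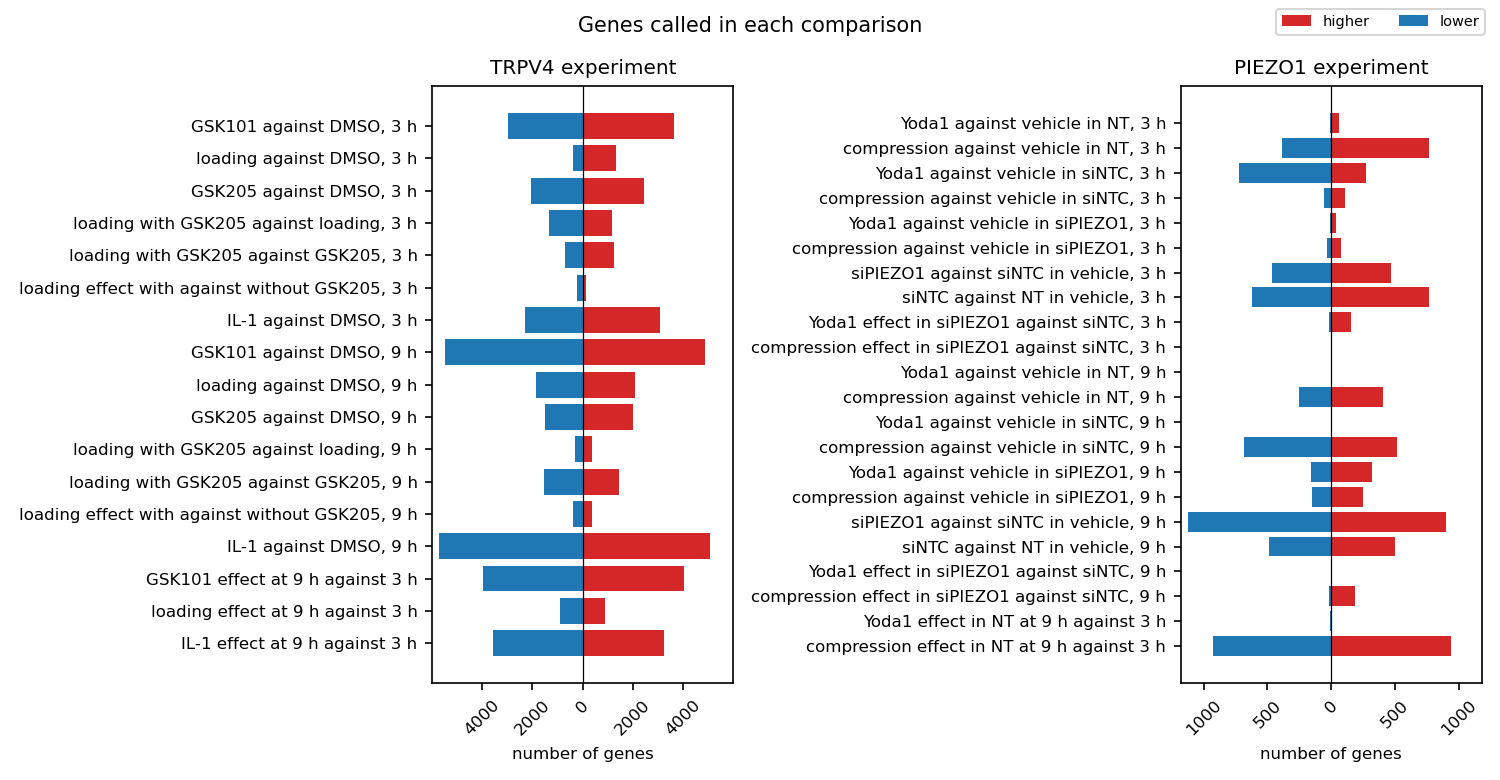
Number of genes (horizontal axes, which differ between the panels) called higher (red, to the right) and lower (blue, to the left) at an adjusted p under 0.05 in each comparison. The most were 10764, for IL-1 at 9 h, and Yoda1 in NT at 9 h had 0.

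Yoda1, the PIEZO1 agonist, moved few genes at 3 h in NT cells. The nuclear receptor gene NR4A2 rose by 1.70 ± 0.20, from 19.9 ± 3.17 to 64.6 ± 4.13 CPM, INHBA by 1.27 ± 0.18, the metalloproteinase gene ADAMTS1 by 1.22 ± 0.18, PTGS2 by 1.06 ± 0.18 and EGR1 by 1.02 ± 0.19. RCAN1 rose by 0.91 ± 0.11. The retinoic acid-degrading enzyme gene CYP26B1 (-1.03 ± 0.21) and ID3 (-0.58 ± 0.11) fell. Immediate early genes were called higher as a list (median 0.55; adjusted p = 0.046), with 3 of 24 members past the test over all genes tested and 17 adjusted over the list alone. Of 9 lists called, 8 were lost with an estimated correlation, among them calcineurin and CREB targets (2 of 16 rose, 4 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Yoda1 called 75 genes in NT at 3 h, 62 higher and 13 lower, and 230 by DESeq2. Leaving out 1 library gave counts between 13 (without NT vehicle replicate 1) and 394 (without NT vehicle replicate 4).

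In transfected cells at 3 h Yoda1 raised NR4A2 by 1.53 ± 0.20 with siNTC and 1.39 ± 0.20 with siPIEZO1. With siNTC the regulators RGS16 (1.15 ± 0.22) and DUSP6 (1.14 ± 0.19) rose, and the tRNA exporter gene XPOT fell by 1.41 ± 0.18. With siPIEZO1, EGR2 (1.91 ± 0.30), PTGS2 (1.60 ± 0.18) and EGR1 (1.27 ± 0.19) rose. Immediate early genes were called higher with siNTC (13 of 24 rose, 15 adjusted over the list alone; adjusted p = 0.095 with an estimated correlation) and with siPIEZO1 (7 of 24 rose, 16 adjusted over the list alone; adjusted p = 0.011). Yoda1 called 989 genes with siNTC (269 higher, 720 lower) and 48 with siPIEZO1 (38 higher, 10 lower). By DESeq2 these were 1629 and 157 (106 higher, 51 lower), and with only the compared groups in the model 21 and 7. With 1 library left out they fell as low as 229 (without siNTC Yoda1 replicate 2) and 14 (without siPIEZO1 Yoda1 replicate 4).

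At 9 h edgeR called 0 genes for Yoda1 in NT (1580 at an unadjusted p under 0.05, 17 by DESeq2) and 0 with siNTC (982, 2 by DESeq2). With siPIEZO1 it called 472 (316 higher, 156 lower), with ID1, an inhibitor of differentiation, at 1.31 ± 0.21. This count fell to 43 without siPIEZO1 vehicle replicate 4 and was 2 with only those 8 libraries in the model. In NT the Yoda1 effect at 9 h differed from that at 3 h for 20 genes (5 without NT vehicle 3 h replicate 1, 57 without NT vehicle 3 h replicate 4). Among these were NR4A2 (-1.46 ± 0.26), SPRY2, a feedback inhibitor of growth factor signalling (-1.01 ± 0.21), and IHH (1.48 ± 0.33).

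A single compression to 80% raised inflammatory and calcium-linked genes at 3 h in NT cells. NR4A3 rose by 3.71 ± 0.48, NR4A2 by 2.55 ± 0.21, the neutrophil chemokine genes AMCF-II and CXCL8 by 3.35 ± 0.39 and 2.35 ± 0.37, and CCL20 by 1.95 ± 0.35. PTGS2 rose by 2.61 ± 0.19, from 56.7 ± 10.5 to 347 ± 128 CPM, and FOSB by 2.26 ± 0.25. ADAMTS1 rose by 1.92 ± 0.18, INHBA by 1.71 ± 0.18 and MMP3 by 1.29 ± 0.16. The haem oxygenase gene HMOX1 (-1.53 ± 0.13), the mineralisation enzyme gene PHOSPHO1 (-1.58 ± 0.38) and CHAC1 (-1.38 ± 0.12), a stress response gene whose enzyme degrades glutathione, fell. NF-kB genes (17 of 31 rose and 0 fell, 20 and 1 adjusted over the list alone; median 0.69; adjusted p = 0.011) and calcineurin and CREB targets (6 of 16 rose and 0 fell, 9 and 1 adjusted over the list alone; adjusted p = 0.014) were called higher. Of 10 lists called, 8 were lost with an estimated correlation, among them immediate early genes (8 of 24 rose and 1 fell, 10 and 1 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation). Compression called 1149 genes in NT at 3 h, 766 higher and 383 lower. The count was 659, 526 and 728 without NT vehicle replicates 1, 2 and 3, 720 without NT compression replicate 4, and 1927 with a covariate for variation between replicates, chosen after the data were seen.

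In transfected cells at 3 h the early response gene APOLD1 rose under compression by 1.43 ± 0.24 with siNTC and 1.46 ± 0.24 with siPIEZO1. PTGS2 rose by 1.08 ± 0.18 and 1.08 ± 0.18, and CHAC1 fell (log2 fold changes -1.63 ± 0.12 and -1.24 ± 0.12). Genes of the unfolded protein and integrated stress response, to which CHAC1, SESN2 and TRIB3 belong, were called lower with siNTC (2 of 22 fell, 4 adjusted over the list alone; adjusted p = 0.0063) and with siPIEZO1 (2 of 22 fell, 6 adjusted over the list alone; adjusted p = 0.0070). Compression called 167 genes with siNTC (107 higher, 60 lower) and 110 with siPIEZO1 (72 higher, 38 lower). By DESeq2 these were 398 (213 higher, 185 lower) and 304, and with only the compared groups in the model 309 (142 higher, 167 lower) and 2. Without a filter siNTC gave 156 (71 higher, 85 lower), so which direction prevailed there is not settled. Leaving out 1 library they fell as low as 62 (without siNTC vehicle replicate 2) and 25 (without siPIEZO1 compression replicate 3).

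At 9 h after compression the NT cells held higher levels of GAL3ST1 (3.80 ± 0.56), the urocortin gene UCN2 (2.29 ± 0.33), the microfibril gene MFAP4 (2.24 ± 0.44) and the lipopolysaccharide co-receptor gene CD14 (2.16 ± 0.43). Levels were lower for the cell cycle inhibitor gene CDKN1C (-0.71 ± 0.13) and the Wnt receptor gene FZD6 (-0.82 ± 0.20). Of 5 lists called, 0 held with an estimated correlation, and they included cartilage matrix genes (3 of 25 rose and 1 fell, 4 and 1 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). With siNTC, SPR rose by 2.22 ± 0.48 and the deiodinase gene DIO2 fell by 0.94 ± 0.12. With siPIEZO1, the thymidine kinase gene TK1 rose by 3.05 ± 0.42, TRAPPC5 by 2.98 ± 0.28 and ID1 by 2.85 ± 0.22. The genes called were 653 in NT (400 higher, 253 lower), 1196 with siNTC (516 higher, 680 lower) and 405 with siPIEZO1 (250 higher, 155 lower). DESeq2 gave 1216, 1929 and 718 (357 higher, 361 lower). With only the compared groups in the model, NT gave 419 and siNTC 589 (302 higher, 287 lower). With 1 library left out the counts fell as low as 180 (without NT compression replicate 2), 374 (without siNTC compression replicate 3) and 194 (without siPIEZO1 vehicle replicate 4). A covariate for variation between replicates seen at 3 h, chosen after the data were seen, left 72, 234 and 362.

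In NT the compression effect differed between 9 h and 3 h for 1861 genes (936 higher, 925 lower), and for 1205 without NT vehicle 3 h replicate 2. The response receded for NR4A2 (-3.02 ± 0.26), NR4A3 (-3.09 ± 0.75), APOLD1 (-2.87 ± 0.37) and FOSB (-2.60 ± 0.37).

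Transfection states differed before any stimulus. In vehicle, siPIEZO1 libraries held more interferon-induced mRNA than siNTC libraries. The chemokine gene CCL5 was higher by 3.93 ± 0.19 at 3 h (368 ± 119 against 24.2 ± 4.49 CPM) and 3.43 ± 0.15 at 9 h. The antiviral genes were higher too, RSAD2 by 2.34 ± 0.19 and 3.30 ± 0.18 and IFIT2 by 2.29 ± 0.27 and 2.55 ± 0.26. Matrix genes of fibroblasts and cartilage were lower, with the lumican gene LUM at -1.89 ± 0.11 and -1.75 ± 0.11, FN1 at -1.10 ± 0.12 and -1.23 ± 0.11, COL1A2 at -1.27 ± 0.16 and -1.45 ± 0.15, and COMP at -0.89 ± 0.15 and -0.92 ± 0.14. Interferon response genes were called higher at 3 h (12 of 23 rose, 17 adjusted over the list alone; adjusted p = 0.015) and 9 h (16 of 23 rose, 19 adjusted over the list alone; adjusted p = 0.0073). Fibroblast and dedifferentiation markers were called lower at 3 h (8 of 12 fell, 9 adjusted over the list alone; adjusted p = 0.0073) and 9 h (0 of 12 rose and 9 fell, 1 and 10 adjusted over the list alone; adjusted p = 0.0073). Cartilage matrix genes were called lower at 3 h (9 of 25 fell, 13 adjusted over the list alone; adjusted p = 0.022) and 9 h (0 of 25 rose and 10 fell, 2 and 13 adjusted over the list alone; adjusted p = 0.057 with an estimated correlation). The comparison called 929 genes at 3 h (465 higher, 464 lower) and 2017 at 9 h (895 higher, 1122 lower). The counts were 590 without siNTC vehicle replicate 1 at 3 h, and 1310 and 1261 without siNTC vehicle replicates 3 and 4 at 9 h. With only the compared groups in the model they were 244 and 1313 (680 higher, 633 lower), which leaves the prevailing direction at 9 h open, and the 3 h count was 1410 by DESeq2 and 1479 with the covariate for variation between replicates. Without siPIEZO1 vehicle replicate 1, whose fibroblast markers averaged 5.67 log2 CPM against 6.11 to 6.18 in the others at 3 h, 9 of 12 of these markers were called lower (median -0.60), and 11 of 25 cartilage matrix genes (median -0.28).

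Against NT, siNTC vehicle libraries held more mRNA of dividing cells. ANLN, needed for cytokinesis, was higher by 2.00 ± 0.18 at 3 h, TOP2A by 1.54 ± 0.19, and the mitotic kinase gene NEK2 by 1.96 ± 0.25 at 9 h. Cell cycle genes were called higher at 3 h (21 of 23 rose, 22 adjusted over the list alone; adjusted p = 5.4e-05) and 9 h (20 of 23 rose, 21 adjusted over the list alone; adjusted p = 4.2e-05). The collagen gene COL8A2 was lower at both times (-2.25 ± 0.21 and -1.65 ± 0.16), and so was EPYC, a small proteoglycan gene of cartilage (-2.09 ± 0.24 and -1.66 ± 0.24). Interferon response genes were called lower at 3 h (12 of 23 fell, 15 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation). The comparison called 1381 genes at 3 h (760 higher, 621 lower) and 986 at 9 h (496 higher, 490 lower). The counts were 918 without NT vehicle replicate 1 at 3 h, and 620 without NT vehicle replicate 4, 543 without siNTC vehicle replicate 1 at 9 h.

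Whether PIEZO1 siRNA changed the response to a stimulus was tested as an interaction against siNTC. For Yoda1 at 3 h it called 172 genes (153 higher, 19 lower), 519 by DESeq2 and 37 without siPIEZO1 Yoda1 replicate 4. PTGS2 responded more with siPIEZO1 (1.49 ± 0.25). The difference was also positive for the BMP antagonist gene NOG (1.70 ± 0.39), while that for NR4A2 was -0.14 ± 0.28 (adjusted p = 0.88). The Yoda1 interaction at 9 h called 5 genes, 111 (51 higher, 60 lower) by DESeq2 and 0 without siNTC vehicle replicate 2. These 5 have no symbol and were named after their values were seen. ENSSSCG00000041596 responded more with siPIEZO1 (1.70 ± 0.30), and ENSSSCG00000005432 (-1.60 ± 0.30), ENSSSCG00000006050 (-2.13 ± 0.40), ENSSSCG00000034861 (-2.70 ± 0.51) and ENSSSCG00000050767 (-2.18 ± 0.40) responded less. For compression it called 0 genes at 3 h by edgeR (854 at an unadjusted p under 0.05, 0 by DESeq2). The compression interaction at 9 h called 202 (186 higher, 16 lower), 510 (413 higher, 97 lower) by DESeq2 and 60 without siNTC vehicle replicate 3, with ID1 at 2.20 ± 0.30 and TRAPPC5 at 2.50 ± 0.37. In simulated data of the size of the 3 h compression interaction, 36.8% of 2-fold and 55.4% of 4-fold changes were called over 17772 genes.

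The same question was put to a score built likewise from the genes called in NT, relative to the vehicle libraries of each state. The Yoda1 score at 3 h was 0.88 ± 0.12 with siPIEZO1 and 0.49 ± 0.35 with siNTC (SD, n = 4 each, two-sided exact permutation p = 0.057). Without siPIEZO1 vehicle replicate 1 the difference went from 0.39 to 0.26 (exact permutation p = 0.23). The compression score at 3 h was 0.49 ± 0.18 and 0.50 ± 0.09 (exact permutation p = 0.94), and on the 100 called genes of smallest p the difference was -0.20 (exact permutation p = 0.26). The 9 h compression score was 0.39 ± 0.10 with siPIEZO1 and 0.84 ± 0.21 with siNTC (exact permutation p = 0.029, the smallest that the 70 arrangements allow). That test takes the vehicle means as fixed. When each library was instead set against 1 vehicle library of its state, over all 576 pairings, the median exact permutation p was 0.11 (0.029 to 0.26) and the difference is not secure. Without siNTC vehicle replicate 4 it went from -0.45 to -0.28. The 9 h score rests on the comparison whose count fell to 72 with the covariate. The Yoda1 score rests on 75 genes for which chance stays open. No gene was called in NT for a Yoda1 score at 9 h.

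Yoda1 and compression shared genes in NT at 3 h. Of the 62 genes called higher with Yoda1, 55 were called higher under compression, where independent lists would share 2.59, among them NR4A2, PTGS2, INHBA and ADAMTS1. Their correlation across genes was 0.48, and unchanged groups simulated against the shared vehicle libraries gave 0.50. The covariance was 0.243 against 0.0892. With divided controls 15.8 genes on average were higher in both (0.360 for independent lists) and the correlation was 0.06. Against compression in siNTC, which shares no library with Yoda1 in NT, 20 genes were higher in both, where 0.362 were due to independent lists. Their correlation was 0.01. Across experiments, 52 of the genes raised by Yoda1 in NT were also raised by GSK101 at 3 h (13.9 for independent lists), and 238 genes were raised by both loading and compression in NT (62.8 for independent lists), 14 were lowered by both (8.77) and 51 moved in opposite directions (48.8). Correlations were 0.11 and 0.10.

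**Figure D3:**
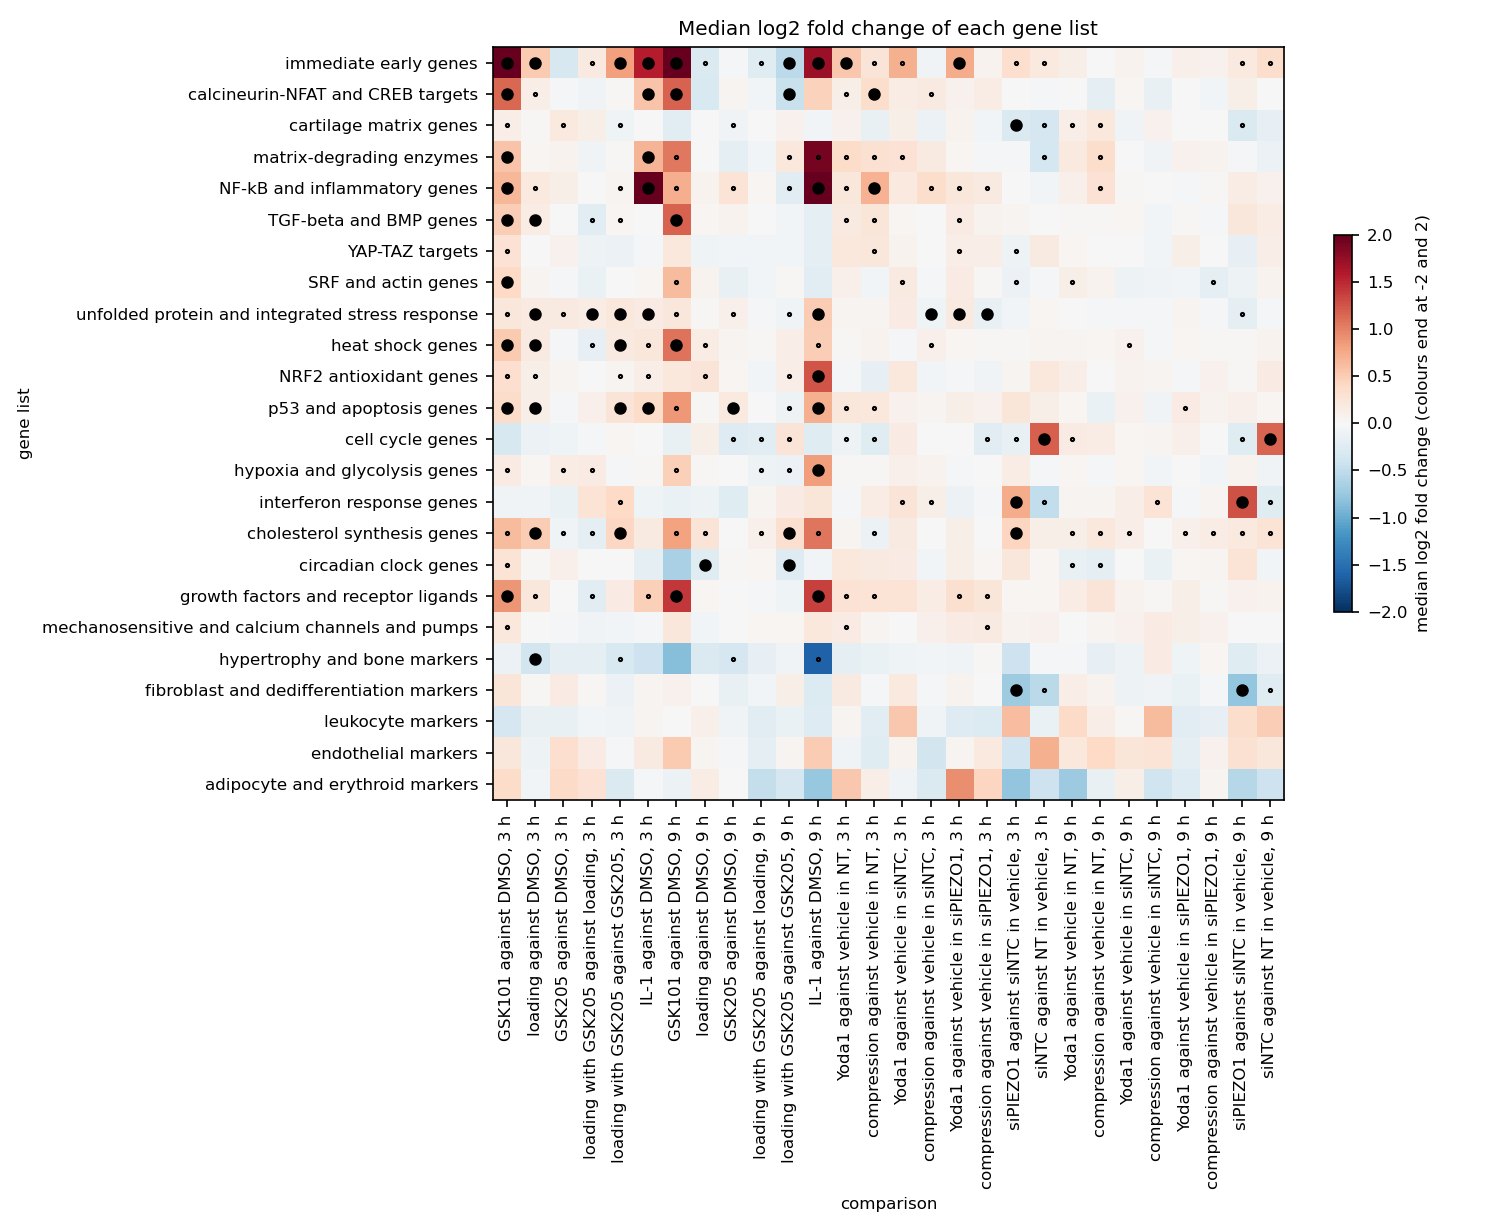
Median log2 fold change (colour, ending at -2 and 2) of each of the 24 gene lists in the comparisons of a pair of groups. Large filled dots mark lists called by camera with an estimated correlation and small open dots those called with the preset correlation alone, and interferon response genes had medians of 0.74 and 1.27 in siPIEZO1 against siNTC at 3 h and 9 h.

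Markers of other cell types were followed as a check on the cultures. Leukocyte, endothelial, and adipocyte and erythroid markers averaged -1.43, -1.07 and -2.24 log2 CPM in DMSO at 3 h, and none of these lists was called in any comparison. Their most abundant members in DMSO were CD74 at 694 CPM, a gene that the interferon response also reaches, EGFL7 and LPL.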

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

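Chosen only after the result was seen were the tests of gene length, of transfection with any small RNA, of a lower yield of small RNAs as a class and of the spread of that yield between libraries, and the splits used for differences between effects. Those splits replaced earlier ones, which let the effects themselves enter. The covariate for variation between replicates, the thinning of deep libraries and the omission of single libraries below were added after the data were seen. The gene length test was first run over all tested genes, too few of which had a length, and the rule for the class yield was changed after its value was known, so that it now stays undecided.

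At 9 h, 118 genes were called and at least 2-fold higher under compression in NT, with a median log2 fold change of 1.43 (interquartile range 0.68). With each library's score on an axis of variation between replicates, taken from the 3 h libraries, as a covariate, their median was 0.59 (interquartile range 0.54), 6 genes were at least 2-fold higher and 65 of the 653 calls were kept. Calls ended because folds shrank, but such a covariate also removes a true effect along the axis. With a replicate block 1043 genes were called. Without 1 library there were 44 (NT compression replicate 2), 56 (NT vehicle replicate 4) or 58 (NT compression replicate 3) such genes, and 173 without NT compression replicate 1. The 110 protein-coding genes among them with a known span were short, with a median of 12.2 kb against 29.5 kb for all protein-coding genes tested. Variation between replicates, single libraries and gene length may each account for part of this rise, and a true late response stays open.

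Interferon response genes were higher in siPIEZO1 than in siNTC vehicle libraries, with a median log2 fold change of 0.74 at 3 h. Without siPIEZO1 vehicle replicate 1, which stood apart, it was 0.63 with 14 of 23 genes called, which argues against that library as the source. Fibroblast markers, on which that library also stood apart, had a median of -0.70 with all libraries and -0.60 without it. Transfection of any small RNA is argued against by siNTC, where the list lay below NT by a median of -0.49. Over the 24 siPIEZO1 libraries, centred by group, the list mean and PIEZO1 gave r = 0.26 (permutation p = 0.28) and rho = 0.17 (permutation p = 0.49), with r = 0.22 without the 2 libraries farthest in PIEZO1. An effect of the extent of PIEZO1 loss cannot be told apart from none. A response to the PIEZO1 siRNA itself or to the partial loss of PIEZO1 may lie behind the difference, and the design, with no further siRNA against PIEZO1, tested neither.

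Of 312 small RNAs tested, 117 were lower and 15 higher with GSK101 at 3 h, with a median log2 fold change of -0.68. Thinned to the mean DMSO total, the GSK101 libraries gave a median of -0.70 and 6376 calls (3482 higher, 2894 lower). Thinning scales all genes alike and cannot test depth as a source. Of the small RNAs 72.8% were lower (exact 95% interval 67.5 to 77.6%), which neither shows nor excludes a lower yield of the whole class. Their share of the counts differed up to 2.25-fold between libraries of 1 group (GSK205 at 9 h) and 2.58-fold between the GSK101 and DMSO means, so uneven recovery of small RNAs between libraries may be the source and stays open. The share of ribosomal RNA (mitochondrial included) was also high in GSK101 libraries. RNA quality was not tested, nor was a biological fall apart from these.

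Every other split of the libraries of a comparison was fitted where there were 35, and for differences between effects 35, or 25 between times, were drawn. The splits argued against chance where only 1 of them, the real one, called as many genes. This held at 3 h for GSK101 (6627 genes, at most 185 in another split), loading (1683, 18), GSK205 (4488, 80), loading with GSK205 against loading (2529, 13) and against GSK205 (1975, 2), and IL-1 (5341, 697). It also held at 3 h for compression in NT (1149, 44), Yoda1 and compression with siNTC (989, 15 and 167, 1), Yoda1 with siPIEZO1 (48, 19), siNTC against NT (1381, 48) and siPIEZO1 against siNTC (929, 811). The last split of 811 exchanged siNTC vehicle replicate 3 with siPIEZO1 vehicle replicate 1, the library that stood apart. At 9 h it held for GSK101 (10307, 2), loading (3926, 2), GSK205 (3510, 231), loading with GSK205 against loading (678, 24) and against GSK205 (2981, 32), and IL-1 (10764, 0). It also held at 9 h for compression in NT (653, 346), with siNTC (1196, 1) and with siPIEZO1 (405, 1), Yoda1 with siPIEZO1 (472, 64), siPIEZO1 against siNTC (2017, 132) and siNTC against NT (986, 471).

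The splits did not argue against chance, with 2 of 35 giving as many genes, for Yoda1 in NT at 3 h (75, 95 in another split) and compression with siPIEZO1 at 3 h (110, 124). With 0 genes called, for Yoda1 at 9 h in NT and with siNTC and for the compression interaction at 3 h, all 35 splits of each must give as many, and these tests say nothing.

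Differences between effects were also singled out because their own test passed. Their splits kept both effects in the model and divided the 4 libraries of each of the 4 groups 2 against 2, so that neither effect enters a split. The loading effect differed with GSK205 for 372 genes at 3 h (at most 1 in another split) and 767 at 9 h (0). The Yoda1 effect differed between siPIEZO1 and siNTC for 172 genes at 3 h (1) and 5 at 9 h (1), and the compression effect for 202 at 9 h (0). Between 9 h and 3 h the GSK101 effect differed for 7998 genes (1), that of loading for 1761 (0), of IL-1 for 6775 (0), of Yoda1 in NT for 20 (1) and of compression in NT for 1861 (2). In each, only 1 of the 35 or 25 splits, the real one, was as large, which argues against a chance division of the libraries. It does not speak to a difference in handling shared by a whole group. The compression score of siPIEZO1 lay below that of siNTC at 9 h by a difference of -0.45. Its exact permutation test passed with the vehicle means taken as fixed, but the median over 576 pairings with single vehicle libraries was p = 0.11, and without siNTC vehicle replicate 4 the difference was -0.28. The spread of the vehicle libraries may thus account for it, and a weaker response with siPIEZO1 stays open.

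In 23 of 288 groups of 4 values, 1 library stood apart from the other 3 by Dixon's test, where chance gives about 1 in 20. PIEZO1 was high in GSK101 3 h replicate 3 (125 CPM) and DMSO 3 h replicate 4 (132 CPM). Loading with GSK205 9 h replicate 2 held 40167217 counts, above the rest of its group. The share of mitochondrial ribosomal and transfer RNA was high in IL-1 3 h replicate 1 (0.586%), NT compression 3 h replicate 4 (0.0665%), siNTC vehicle 3 h replicate 1 (0.0906%), siNTC compression 3 h replicate 4 (0.0823%) and siNTC vehicle 9 h replicate 4 (0.0944%). Leukocyte markers averaged -1.24 log2 CPM in GSK101 3 h replicate 3, -0.73 in NT compression 3 h replicate 1, -0.90 in NT compression 9 h replicate 1 and -1.32 in NT Yoda1 9 h replicate 2, each above the rest. Endothelial markers averaged -2.04 in NT Yoda1 9 h replicate 1. Fibroblast markers averaged 6.16 in loading 9 h replicate 2, 7.30 in NT vehicle 3 h replicate 2, 5.67 in siPIEZO1 vehicle 3 h replicate 1 and 6.86 in siNTC compression 9 h replicate 3. Hypertrophy and bone markers averaged 2.74 in GSK101 3 h replicate 3 and 2.78 in NT vehicle 3 h replicate 2. On the axis of variation between replicates, NT compression 3 h replicate 4 scored -2.08 SD, siPIEZO1 vehicle 3 h replicate 1 scored -1.70, NT vehicle 9 h replicate 4 scored -2.37 and siNTC Yoda1 9 h replicate 4 scored -1.33.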

How the results depend on the processing

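Protein-coding genes only, the replicate-axis covariate, thinning, the omission of libraries from the 2-fold and interferon counts and of vehicle libraries from scores, and the pairing with single vehicle libraries were chosen after the data were seen, and all other alternatives before. With RLE scaling each of the 39 counts stayed within 1.5 times, and none of the named genes turned sign with DESeq2, RLE scaling, no filter, the block, protein-coding genes only or the covariate. The model of only the compared groups and thinning were not tried on them. Of their values, 430 of 433 kept their side of the threshold with DESeq2, 433 of 435 with RLE scaling and 425 of 435 without a filter. The same held for 400 of 400 among protein-coding genes, 144 of 176 with the covariate and 3735 of 4120 with 1 library left out (381 weaker, as fewer libraries were fitted). The side with more calls turned under at least 1 alternative in 18 of 39 contrasts, so small excesses of higher or lower genes settle no direction. Where a count moved, the cause was not tested unless named. The PIEZO1 experiment varied more between libraries (common coefficients 0.282 and 0.300) than the TRPV4 experiment (0.107 and 0.0874). Depth was no limit to the genes named for the size of their change, which held at least 5 CPM in the highest group compared.

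DESeq2 called over 1.5 times as many genes for the loading interaction at 3 h (685), loading with GSK205 against loading at 9 h (1181), siPIEZO1 against siNTC at 3 h (1410), the Yoda1 interaction at 3 h (519) and 9 h (111), the compression interaction at 9 h (510) and Yoda1 between times (37). At 3 h it called 230, 1629 and 157 for Yoda1 in NT, siNTC and siPIEZO1, and 398 and 304 for compression in siNTC and siPIEZO1. At 9 h it called 17, 2 and 892 for Yoda1 and 1216, 1929 and 718 for compression. Without a filter the Yoda1 interaction at 9 h gave 16 genes, and among protein-coding genes 2, as Yoda1 in NT at 9 h gave 1.

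With only the compared groups in the model, and so fewer libraries to estimate the spread, the counts were 1021 for loading at 3 h, 210, 21 and 7 for Yoda1 in NT, siNTC and siPIEZO1 at 3 h. They were 309 and 2 for compression in siNTC and siPIEZO1 at 3 h, and 244 and 1313 for siPIEZO1 against siNTC at 3 h and 9 h. Further counts were 419 and 589 for compression in NT and siNTC at 9 h and 2 for Yoda1 in siPIEZO1 at 9 h. This model was not applied to interactions. With the covariate they were 38 for Yoda1 and 1927 for compression in NT, 573 for Yoda1 in siNTC, 299 for compression in siPIEZO1, 1479 for siPIEZO1 against siNTC and 549 for the Yoda1 interaction at 3 h. They were 72 and 234 for compression in NT and siNTC and 89 and 324 for the Yoda1 and compression interactions at 9 h.

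The replicate block moved 4 counts by over 1.5 times, to 230 for the loading interaction at 3 h and, at 9 h, to 3 for Yoda1 in NT, 1043 for compression in NT and 88 for the Yoda1 interaction. Replicate numbers did not meet the bar for pairs, a correlation over 0.1 in every pair. Over genes with a mean of at least 5 CPM only 16 of 60, 11 of 60, 46 of 144 and 65 of 144 pairs did so in the 4 models of a single time, and 4 of 24, 3 of 24, 9 of 36 and 15 of 36 libraries lay closest to their own number. On all tested genes, checked first, the bar was missed too. In the PIEZO1 experiment at 9 h, though, libraries of the same number correlated at 0.09 on average against -0.03 for others. On the replicate axis, replicate 4 lay below its group mean in 9 of 9 groups. Replicate 2 did so in 0 of 9, at 3 h too. Libraries of 1 number thus shared some variation there, which the bar misses and the main calls ignore.

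With 1 library left out, counts moved by over 1.5 times as follows. For loading at 3 h the count was 1110 without DMSO replicate 4, 1057 without loading replicate 3 and at most 1759 without any other. For loading with GSK205 against loading it was 1596 without loading replicate 1 and at most 2524 without any other at 3 h and 295 and 347 without loading with GSK205 replicates 1 and 3, 320 without loading replicate 1 and at most 746 without any other at 9 h. For the loading interaction it was 239, 170 and 243 without GSK205 replicates 1, 2 and 3, 671, 217 and 196 without DMSO replicates 1, 2 and 4, 135 without loading with GSK205 replicate 1, 214 and 159 without loading replicates 2 and 3 at 3 h and 505 without DMSO replicate 2 and at most 896 without any other at 9 h. For loading between times it was 1129 without loading 3 h replicate 1 and at most 2175 without any other.

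For Yoda1 in NT at 3 h the count was 13, 20, 34 and 394 without NT vehicle replicates 1, 2, 3 and 4, 24, 39 and 38 without NT Yoda1 replicates 1, 2 and 3. With siNTC it was 440, 528 and 593 without siNTC vehicle replicates 1, 2 and 4, 229 without siNTC Yoda1 replicate 2 and at most 1223 without any other, and with siPIEZO1 24, 25, 89 and 25 without siPIEZO1 vehicle replicates 1, 2, 3 and 4, 20, 16 and 14 without siPIEZO1 Yoda1 replicates 2, 3 and 4. The 9 h counts were 2 without NT Yoda1 replicate 2 and at least 0 without any other in NT, and 174 and 43 without siPIEZO1 vehicle replicates 2 and 4, 134 and 223 without siPIEZO1 Yoda1 replicates 2 and 3 and at most 673 without any other. For Yoda1 between times it was 5, 12 and 57 without NT vehicle 3 h replicates 1, 2 and 4, 11 without NT Yoda1 3 h replicate 1. The Yoda1 interaction gave 50, 53, 86 and 38 without siNTC vehicle replicates 1, 2, 3 and 4, 86 and 297 without siNTC Yoda1 replicates 2 and 4, 68 without siPIEZO1 vehicle replicate 4, 52, 57 and 37 without siPIEZO1 Yoda1 replicates 2, 3 and 4 at 3 h, and 2, 0 and 28 without siNTC vehicle replicates 1, 2 and 4, 21, 3, 1 and 0 without siNTC Yoda1 replicates 1, 2, 3 and 4, 29, 0, 29 and 0 without siPIEZO1 vehicle replicates 1, 2, 3 and 4, 0, 2 and 18 without siPIEZO1 Yoda1 replicates 1, 2 and 4 at 9 h.

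For compression in NT at 3 h the count was 659, 526 and 728 without NT vehicle replicates 1, 2 and 3, 720 without NT compression replicate 4 and at most 1583 without any other. Compression at 3 h gave 62, 80 and 93 without siNTC vehicle replicates 2, 3 and 4, 85, 98 and 64 without siNTC compression replicates 2, 3 and 4 and at most 189 without any other with siNTC. With siPIEZO1 it gave 47 without siPIEZO1 vehicle replicate 3, 71, 25 and 28 without siPIEZO1 compression replicates 2, 3 and 4 and at most 117 without any other. Compression at 9 h gave 405 and 284 without NT vehicle replicates 3 and 4, 180 and 328 without NT compression replicates 2 and 3 and at most 797 without any other in NT. With siNTC it gave 561 and 445 without siNTC vehicle replicates 3 and 4, 717 and 374 without siNTC compression replicates 2 and 3 and at most 1393 without any other, and with siPIEZO1 194 without siPIEZO1 vehicle replicate 4, 222 without siPIEZO1 compression replicate 2 and at most 463 without any other. For compression between times it was 1205 without NT vehicle 3 h replicate 2 and at most 2165 without any other. The compression interaction gave 1 without siNTC compression replicate 1 and at least 0 without any other at 3 h and 60 and 91 without siNTC vehicle replicates 3 and 4, 357 and 65 without siNTC compression replicates 1 and 3, 80, 331 and 64 without siPIEZO1 vehicle replicates 2, 3 and 4, 91 without siPIEZO1 compression replicate 1 at 9 h. For siPIEZO1 against siNTC the count was 590 without siNTC vehicle replicate 1 and at most 1355 without any other at 3 h and 1310 and 1261 without siNTC vehicle replicates 3 and 4 and at most 2039 without any other at 9 h. For siNTC against NT it was 918 without NT vehicle replicate 1 and at most 1569 without any other at 3 h and 620 without NT vehicle replicate 4, 543 without siNTC vehicle replicate 1 and at most 1212 without any other at 9 h.

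Taken on the 100 called genes of smallest p, the GSK101 score of loading with GSK205 lay below loading at 3 h by a difference of -0.19 (exact permutation p = 0.029, n = 4 each), and at 9 h the difference turned to -0.037, as it did with a prior count of 0.5 (-0.0054). With 1 library left out it ran from -0.11 (without loading replicate 4) to -0.041 (without loading with GSK205 replicate 1) at 3 h and from -0.0071 (without loading replicate 2) to 0.0077 (without loading with GSK205 replicate 4) at 9 h. The Yoda1 score difference of siPIEZO1 from siNTC ran from 0.23 (without siNTC Yoda1 replicate 4) to 0.50 (without siNTC Yoda1 replicate 2, exact permutation p = 0.029). That of compression ran from -0.090 (without siPIEZO1 vehicle replicate 1) to 0.051 (without siPIEZO1 compression replicate 1) at 3 h and from -0.56 (without siNTC vehicle replicate 2) to -0.28 (without siNTC vehicle replicate 4) at 9 h. Over all pairings of libraries with single vehicle libraries, the 9 h compression difference of -0.45 had a median exact permutation p of 0.11, and the Yoda1 difference of 0.39 one of 0.17. Over genes of at least 10 CPM the median correlation between responses was 0.31 against 0.27, and that of Yoda1 in NT with compression in siNTC turned from 0.01 to -0.18 at 3 h and from -0.01 to 0.42 at 9 h. With an estimated correlation 73 of 245 list calls held, and fry kept 213. Of 9 calls of hypertrophy and bone (5) and fibroblast (4) markers 3 held, and over all marker lists fry called 39. The effect of GSK101 on SH3BGR at 9 h against 3 h turned to -0.76 without GSK101 9 h replicate 3, from which the rise came, against up to 5.06 without replicate 2. For NR4A2 the Yoda1 interaction at 3 h ran from -0.36 (without siNTC Yoda1 replicate 4) to 0.069 (without siNTC Yoda1 replicate 2).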

Other observations

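Fibroblast and dedifferentiation markers were called lower in siNTC against NT as well, at 3 h (1 of 12 rose and 6 fell, 1 and 7 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation) and 9 h (1 of 12 rose and 5 fell, 1 and 6 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), with the preset correlation alone. The knockdown libraries differed in TRPV4 too. Over the 3 stimuli together, a contrast added after the data were seen, TRPV4 was higher in siPIEZO1 than in siNTC by 0.29 on the log2 scale at 3 h (edgeR adjusted p = 0.0033, 12 against 12 libraries) and by 0.16 at 9 h (adjusted p = 0.15), where the test was not passed.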
